A study of Anser sp. with 4 samples.

How the data were processed

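Total RNA from ventral skin of female geese was hybridised to 4 one-colour arrays labelled with Cy3, 1 array each for skin taken before molt and at 1.5, 5 and 10 days after molt. The labels name 6 geese reared apart for the experiment and sampled at each time, and do not say whether their RNA was pooled or which bird gave which sample. Per the file headers, the array design carries probes annotated on the chicken build galGal3, so that goose RNA was read by probes made for another bird. A difference in sequence between goose and chicken lowers the signal of a probe, and a probe can also take up signal from related transcripts. Log2 ratios between arrays compare each probe with itself.

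The authors' scanner files hold spot intensities. Per the submitters' processing notes they were made with Agilent Feature Extraction 10.7, and per the file headers with release 10.7.3.1, in 1 scan of 1 slide that held all 4 arrays. The processed intensity in the deposited files is already background-subtracted by that program and is not scaled between arrays. The deposited series table holds log2 values. Its 43603 rows all matched a probe, each column correlated best with its own array's processed signal (r between 0.9995 and 0.9999 against at most 0.983 with another array), and all 4 columns had the same median of 3.74, as after quantile normalization between arrays. How the authors made that table is not given in the sources used here.

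Probes are identified in the files by 31533 transcript identifiers, mostly chicken Ensembl and RefSeq accessions, of which 23852 have 1 probe and 7681 have 2 or more. The files pair 0 of them with a gene symbol, and no annotation table was used here. The 35 gene lists that had been fixed before the data were examined (keratins, Wnt, BMP, Hedgehog, cell cycle, muscle, blood and others) could therefore not be matched, the 3 planned counts of shifted lists were not run, and markers of other cell types were not read. Results are given per transcript identifier, and chromosome positions were not used here. The naming rule fixed beforehand allowed, with no gene names, at most 2 identifiers each way, taken as those with the largest log2 ratio among identifiers well above background on both arrays whose detected probes all lay on 1 side of 0. The report prints 4 of those it chose, 2 each way. The lower 2 are the largest at 5 days, and the higher 2 are those chosen in 2 comparisons.

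Processed signals were put on the log2 scale and each array's 75th percentile over its 43803 non-control spots was subtracted. At least 52.4% of the spots were well above background on every array, as Feature Extraction flags it, and 0 were saturated. Spots flagged as outliers on any array were left out, which removed 39 probes. Repeated spots of a probe were averaged, and then the probes of an identifier that were well above background on at least 1 of the arrays compared. A dim value was set to the higher of its own value and the lowest value well above background on its array, so that a ratio with a dim side is a bound. An identifier was counted as higher or lower at 2-fold (1 on the log2 scale). The software was Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and limma 3.58.1 under R 4.3.3 for 1 alternative background correction.

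With 1 array per time there is no replicate, no test was made between times and no p-value is given. In their place, 3 kinds of technical error were measured. The first is the SD of repeated spots of 1 probe. The second is the SD of log2 ratios between different probes of 1 identifier, which also holds splice forms, cross-hybridisation and sequence differences. The third is how far a ratio found on some of an identifier's probes was seen on its other probes. None of them holds the difference between birds or between RNA preparations. The number of arrays limits the precision of every value. The counts that the spread between probes alone would give were obtained by drawing residuals of probes about their identifier's mean (20 draws). The residuals came from probes well above background on both arrays, pooled over all levels, and were given to every identifier compared. Dimmer probes spread more, so these counts may be too low for dim identifiers and for ratios that are bounds. Overlaps of calls that share the array from before molt were set beside simulated unchanged arrays, with equal noise and, chosen after seeing the data, with a spread per array solved from the pairwise spreads between probes (20 draws). The equal noise was drawn as if each identifier had 1 probe. The solved spread was reduced for the number of probes in use, so these simulations differ in both respects.

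The counting was tested on simulated data for the comparison of 1.5 days with before molt, over 19959 identifiers with noise of 0.456 log2 per array. This is the SD of the log2 ratio between probes in that comparison (0.65, over all identifiers with 2 or more probes) divided by the square root of 2. Dimmer probes spread more. It called 100% of 50 identifiers changed 4-fold, 84.0% of 50 changed 3-fold, 42.0% of 50 changed 2-fold and 22.0% of 50 changed 1.5-fold, and 10.1% of the unchanged identifiers. Alternatives fixed beforehand were quantile normalization, median centring, normexp background correction (offset 50, on the median spot signal because the files hold no mean signal), a stricter and no filter on dim probes, the brightest probe of an identifier, and the authors' log2 table. Scaling on spike-in probes and a restriction to identifiers with 2 or more probes were added after seeing the data.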

Results

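Gene expression in ventral skin of geese was measured at 4 times around the molt, with 1 array each for skin taken before molt and at 1.5, 5 and 10 days after molt. The series is about feather regeneration, and the comparisons with the sample before molt ask which transcripts stood apart from it as regeneration went on. On the arrays, 18883 transcript identifiers were well above background before molt, 18486 at 1.5 days, 17061 at 5 days and 18005 at 10 days. Over all times 20386 of 31533 identifiers were detected, which was 82.7% of the identifiers named by a RefSeq mRNA and 68.7% of those named by a chicken Ensembl transcript. The 100 brightest spots held 44.2% of all non-control signal before molt, 35.8% at 1.5 days, 40.1% at 5 days and 43.6% at 10 days. Each group had 1 array, so no value has a replicate error and a difference between arrays holds the difference between samples as well as that between times.

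The technical error within the slide was small for repeated spots and larger between probes. For 25 probes spotted 5 times and well above background throughout, the SD of the log2 ratio between 2 arrays was 0.12 to 0.16 over the 5 comparisons. For identifiers read by 2 or more probes, the SD between their probes was 0.65 for 1.5 days against before molt, 0.63 for 5 days against before molt and 0.50 for 10 days against before molt. It was 0.34 for 5 days against 1.5 days and 0.48 for 10 days against 5 days. For 5 days against before molt it was 0.45 over probes whose mean level was above the 75th percentile and 0.73 over dimmer ones. An identifier read by 1 probe carries this second error in full.

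Skin at 1.5 days differed widely from skin before molt, and more identifiers were lower than higher. Of 19945 identifiers compared, 1651 were at least 2-fold higher and 2700 at least 2-fold lower, and at 4-fold the numbers were 159 higher and 737 lower. BX933126, read by 1 probe, stood 16.9-fold higher than before molt, and ENSGALT00000020769, also read by 1 probe, 23.6-fold higher. The second was dim before molt, at -3.35 where the detection bound was -4.06, and its log2 ratio of 4.56 was 2.48 after normexp correction. ENSGALT00000018733 was among the lower identifiers, 34.8-fold below its level before molt. For 254 of the higher and 625 of the lower identifiers the dim side was not well above background and the ratio is a bound. The spread between probes alone would give 1736 of the 4351 identifiers past 2-fold in either direction and 284 of the 896 past 4-fold. These counts pool probes of all levels. Identifiers ranked below 10000 by mean signal held 838 of the higher and 1705 of the lower calls. The SD between probes was 0.77 for probes at or under the 75th percentile and 0.47 above it, so the spread may account for more. Of the identifiers past 2-fold with 2 or more probes in use, 117 of 302 higher and 93 of 282 lower had every probe past 2-fold in the same direction, and of those past 4-fold 15 of 19 higher and 31 of 34 lower. The balance of directions depended on the scaling and on the identifiers taken. Higher identifiers made up 37.9% of those past 2-fold, 49.4% after median centring, 2.13% after scaling on spike-in probes, and 48.2% over identifiers with 2 or more probes.

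At 5 days more identifiers lay far below their level before molt than at 1.5 days, 139 against 52 at 16-fold. There were 1749 identifiers at least 2-fold higher and 2476 at least 2-fold lower of 19456 compared. At 4-fold 197 were higher and 830 lower, and at 16-fold 4 were higher. ENSGALT00000018733 was 336-fold lower than before molt, with a log2 signal relative to the 75th percentile of 8.77 before molt and 0.38 at 5 days. ENSGALT00000035537, at 10.81 before molt, was 322-fold lower at 2.48. Each was read by 1 probe. BX933126 was 16.3-fold above its level before molt, a log2 ratio of 4.03 that was 3.26 after normexp correction. The spread between probes alone would give 1541 of the 4225 identifiers past 2-fold and 273 of the 1027 past 4-fold. With 2 or more probes in use, 158 of 316 identifiers past 2-fold higher and 90 of 253 past 2-fold lower had every probe past 2-fold in the same direction, and 24 of 28 and 40 of 52 of those past 4-fold. Higher identifiers made up 41.4% of those past 2-fold, against 55.3% after median centring, 19.6% after normexp correction, 8.73% after spike-in scaling and 52.4% over identifiers with 2 or more probes.

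**Figure D1:**
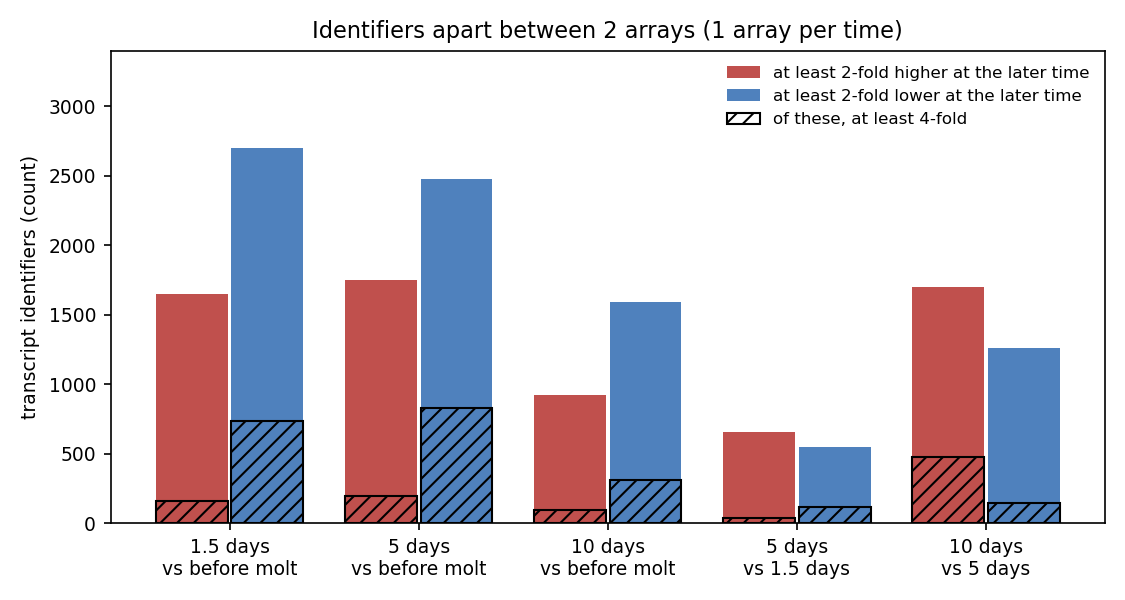
Number of transcript identifiers (vertical axis) at least 2-fold higher (red) or lower (blue) at the later time in each comparison of 2 arrays, with those past 4-fold hatched. The lower identifiers reach 2700 at 1.5 days and 2476 at 5 days against before molt, and 1594 at 10 days.

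At 10 days fewer identifiers stood apart from before molt. Of 19499 compared, 920 were at least 2-fold higher and 1594 at least 2-fold lower, and at 4-fold 93 were higher and 309 lower. ENSGALT00000018733 was 1.83-fold and ENSGALT00000035537 1.53-fold above their levels before molt, which on the log2 scale is 0.87 and 0.61 against an SD of 0.50 between probes of 1 identifier in this comparison. ENSGALT00000020769 was 23.9-fold higher than before molt at this time, a log2 ratio of 4.58 that was 2.50 after normexp correction. It had been 8.77-fold higher at 5 days. BX933126 was 7.79-fold higher than before molt. The spread between probes alone would give 909 of the 2514 identifiers past 2-fold and 64.2 of the 402 past 4-fold. With 2 or more probes in use, 40 of 119 identifiers past 2-fold higher and 46 of 155 past 2-fold lower had every probe past 2-fold in the same direction. Higher identifiers made up 36.6% of those past 2-fold, 23.0% after normexp correction, 9.25% after spike-in scaling, 45.6% after median centring and 43.5% over identifiers with 2 or more probes.

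The comparisons of successive times placed the smallest step between 1.5 and 5 days. From 1.5 to 5 days 654 of 18858 identifiers were at least 2-fold higher and 550 at least 2-fold lower, 1204 in all, where the spread between probes alone would give 266. The balance turned at larger folds, with 39 higher and 118 lower at 4-fold and 1 higher and 10 lower at 16-fold. From 5 to 10 days 1702 of 18821 were higher and 1261 lower, 2963 in all, with 720 from the spread between probes alone. At 4-fold, 476 were higher and 144 lower from 5 to 10 days, and at 16-fold 62 were higher and 2 lower. Higher identifiers made up 54.3% of those past 2-fold from 1.5 to 5 days, 14.4% after normexp correction and 85.3% after spike-in scaling. From 5 to 10 days they made up 57.4%, against 80.6% after normexp correction and 71.4% after spike-in scaling, and 49.2% after median centring, which turned the balance. Across the 21112 probes well above background on all arrays, the correlation of log2 signals was highest between 1.5 and 5 days (Pearson r 0.982), then between before molt and 10 days (0.969), and lowest between before molt and 5 days (0.936). These are correlations across probes, which are not independent replicates.

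Identifiers were also grouped by the times at which they stood apart from all others by 2-fold or more. Every group uses all 4 arrays, so the groups are not independent of each other. Lower at both 1.5 and 5 days than at both before molt and 10 days were 772 identifiers, and 260 were higher at those times. The numbers were 213 and 26 under normexp correction and 1483 and 40 under spike-in scaling. The other ways of dividing the 4 arrays into pairs gave 40 identifiers higher and 14 lower at 5 and 10 days, and 8 higher and 17 lower at 1.5 and 10 days. Of single times, before molt stood apart most often, with 739 identifiers higher and 353 lower than at each later time, against 220 and 34 under normexp correction and 2189 and 60 under spike-in scaling. Counts that the spread between probes alone would give were not computed for any of these groups. Noise on a single array can by itself set an identifier apart at that time. At 1.5 days 90 were higher and 207 lower, at 5 days 140 were higher and 316 lower, and at 10 days 172 were higher and 324 lower than at each other time. The balance at 1.5 days turned under normexp correction, with 51 higher and 5 lower, and was 13 higher and 753 lower under spike-in scaling.

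**Figure D2:**
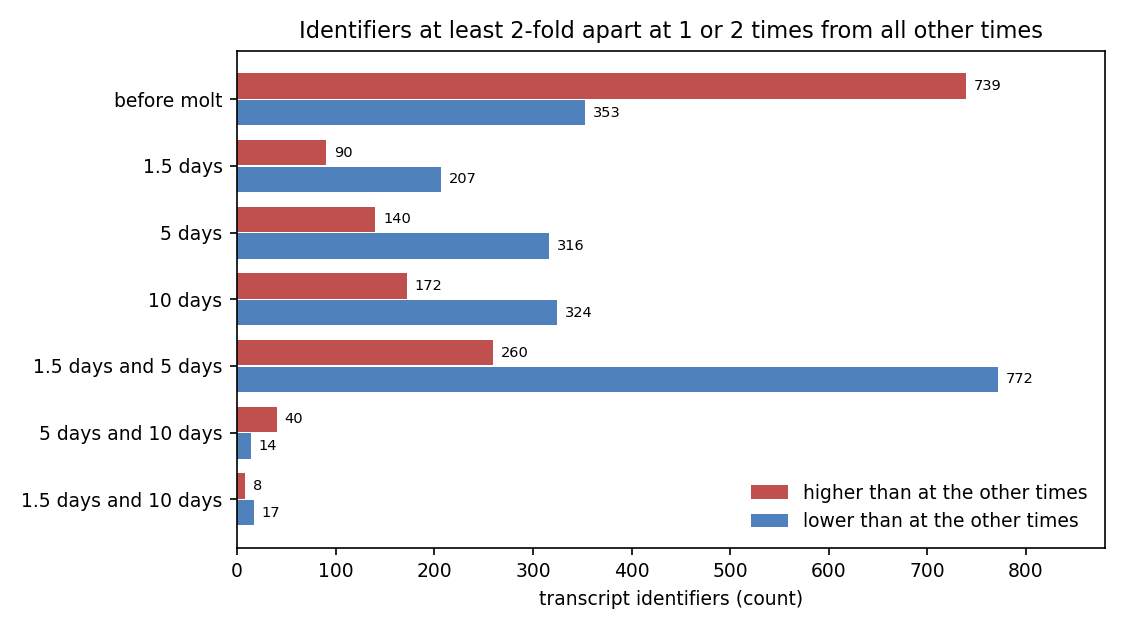
Number of transcript identifiers (horizontal axis) at least 2-fold higher (red) or lower (blue) at the named time or pair of times than at every other time, over 20386 identifiers. The pair 1.5 and 5 days has 772 lower and 260 higher identifiers, and the pair 5 and 10 days has 40 higher and 14 lower.

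The calls at 1.5 and 5 days against before molt overlapped. Of 19284 identifiers compared at both times, 1036 were higher and 1832 lower at both. Independent lists of these sizes would share 138 and 347. Both comparisons use the same array from before molt, and simulated unchanged arrays shared 324 and 330 with equal noise of 0.456 log2 on every array, the value for 1.5 days against before molt, as if each identifier had 1 probe. Solving for each array from the 3 pairwise spreads between probes gave SDs of 0.59 before molt, 0.26 at 1.5 days and 0.22 at 5 days, and unchanged arrays simulated so, with the noise reduced for the number of probes in use, shared 520.1 and 522. These SDs depend on the arrays solved together. With 5 and 10 days they were 0.46 before molt, 0.43 at 5 days and 0.20 at 10 days, so no single spread per array held. The array could not be split, so part of the excess may come from the shared control. Calls at 10 days shared 503 higher and 852 lower identifiers with those at 5 days, where independent lists would share 69.7 and 207. Simulated unchanged arrays shared 285 and 339 with the same equal noise, and 177 and 171 with the spread solved for each array.

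Some identifiers had a deep trough at 5 days. Those at least 16-fold lower at 5 days than at both before molt and 10 days were collected, a choice made after the values were seen. There were 52, and 15 of them were among the 100 brightest identifiers by mean signal over the 4 arrays. For the 52, the median level was 6.89-fold below that before molt at 1.5 days, 70.7-fold below at 5 days and 1.26-fold below at 10 days. The fall at 5 days and the return at 10 days follow in part from the choice of the set. Whatever their level at 10 days, 139 identifiers were at least 16-fold lower at 5 days than before molt. All 52 were at least 2-fold lower at 1.5 days than before molt, and 50 were at least 2-fold higher at 10 days than at 1.5 days. At 5 days 6 of the 52 were not well above background. Of the 52, 2 were read by more than 1 probe in use, and in both every probe was at least 2-fold lower at 5 days. No identifier (0 of 20386) was at least 16-fold higher at 5 days than at both before molt and 10 days. Near-identical copies of a transcript cannot be told apart by these probes, so the number of separate genes in the set is uncertain.

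**Figure D3:**
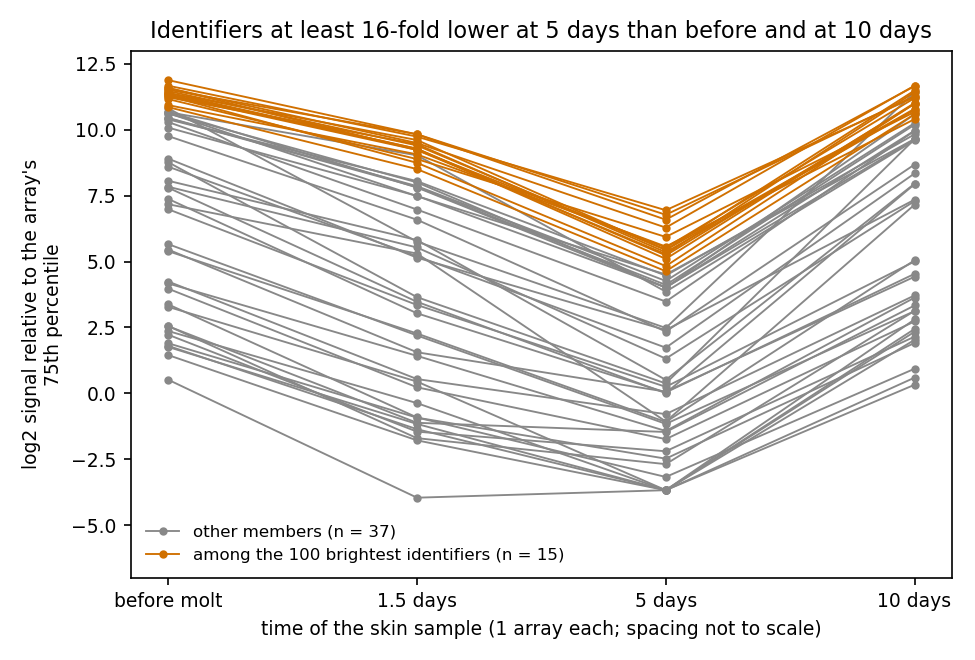
Log2 signal relative to each array's 75th percentile (vertical axis) at the 4 times (horizontal axis, 1 array each) for the 52 identifiers at least 16-fold lower at 5 days than before molt and at 10 days, a line per identifier. The 15 members among the 100 brightest identifiers (orange) and the 37 others (grey) are lowest at 5 days except where a member lies at the detection bound.

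Among identifiers ranked brightest by mean signal over all arrays, the trough was limited to part of them. This ranking includes the signal at 5 days, so a trough by itself lowers an identifier's rank. ENSGALT00000035537, at 10.81 before molt and 11.43 at 10 days, was not among the 100. The share of bright identifiers with a trough may therefore be understated, and a ranking without the array of 5 days was not made. Among the 100 brightest identifiers, 16 were at least 2-fold lower at 5 days than before molt, 15 of these at least 16-fold, and 2 were at least 2-fold higher. The median of the 100 was -0.05 on the log2 scale. At 10 days 1 of the 100 was at least 2-fold lower and 0 were higher. Among identifiers ranked below 10000 by mean signal, 15.7% were lower and 9.80% higher at 5 days.

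Calls at 5 days were also read on separate probes. For identifiers with 2 or more probes, those at least 2-fold higher or lower at 5 days on alternate probes were read again on the remaining probes. The 435 chosen as higher had a median log2 ratio of 0.78 on the remaining probes at 5 days, with 40.2% still past 2-fold. At 1.5 days it was 0.56 and at 10 days 0.30. The 374 chosen as lower had a median of -0.19 on the remaining probes at 5 days, with quartiles of -0.98 and 0.39, and 24.6% still past 2-fold. At 1.5 days their median was -0.23 and at 10 days -0.08. The difference between the 2 directions was not tested.

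**Figure D4:**
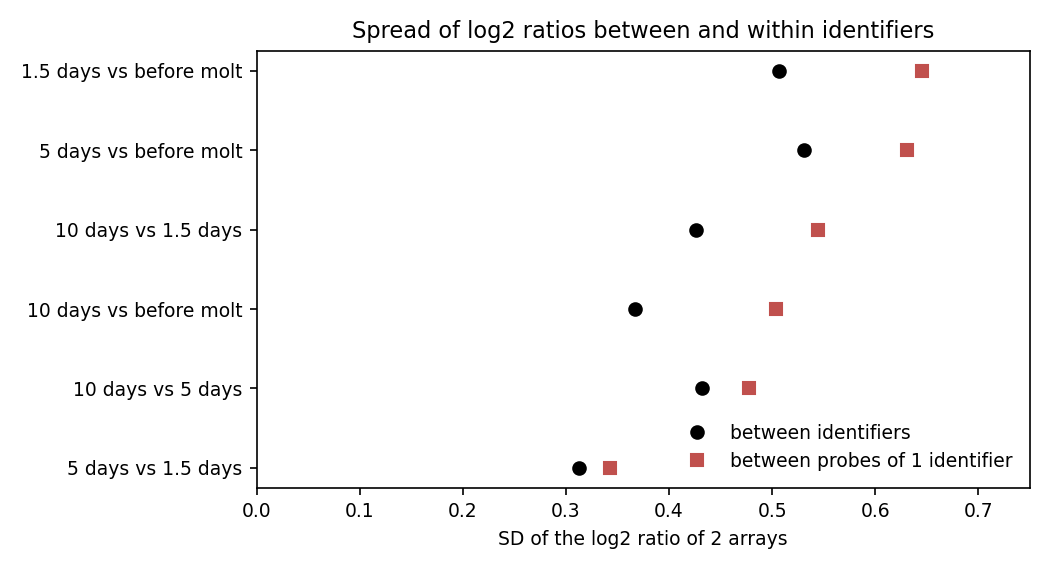
SD of the log2 ratio of 2 arrays (horizontal axis) between identifiers (black circles) and between probes of 1 identifier (red squares), for each of the 6 pairs of arrays, over identifiers with 2 or more probes. Both are smallest for 5 days against 1.5 days, at 0.31 and 0.34, and the spread between probes is the larger in every pair. Over brighter probes alone (not drawn) that between identifiers is the larger, as for 5 days against before molt, at 0.59 against 0.45. The exception is 10 days against before molt, at 0.37 between identifiers and 0.39 between probes.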

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

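All tests in this part were chosen after the result was seen. The spike-in control RNAs (E1A), used in none of the comparisons, stood higher against the goose signal after molt than before it. Over 6 mid-range spike-in probes with 32 spots each, the mean log2 shift relative to the 75th percentile was 0.92 ± 0.09 (SD over the 6 probes) at 1.5 days, 0.57 ± 0.06 at 5 days and 0.40 ± 0.07 at 10 days, each against before molt. At 1.5 days the shift was 1.05 after median centring, which argues against the percentile used for scaling as its cause. It was alike over the spike-in probes, with a range of 0.19 at 1.5 days, which is what a larger amount of spike-in would give, and equally a smaller share of messenger RNA in the total RNA. With 1 array per time these cannot be told apart, and a change in the skin itself stays open as well. If the spike-ins were taken as the true scale, 9134 identifiers would be at least 2-fold lower at 1.5 days instead of 2700, so the counts in the report are relative to the bulk of the signal on each array.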

How the results depend on the processing

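With 1 array per time, no replicate could be left out and no slide block fitted. The planned gene list counts were not run. The SD of repeated spots was recomputed under quantile normalization, median centring, normexp and no filter, and was not recomputed under the other settings. Of 21 counts of identifiers, all 21 stayed within 1.5 times their value under quantile normalization, median centring, the brightest probe and the authors' log2 table. Detection on every array compared kept 16 of 21, spike-in scaling (chosen after seeing the data) 7, no filter 5 and normexp 2. Each log2 ratio tracked for the identifiers chosen by the naming rule kept its direction wherever it was computed, though not its size. Signal over background limits the counts, since no filter admits probes at background. Spike-in scaling by construction shifts every ratio of a comparison alike. The normexp setting changed the input signal along with the correction and its offset of 50. Median processed signals were 11.3 to 15.2 over the arrays, and adding a constant larger than the signal draws ratios of dim spots toward no change. Smaller counts under normexp are therefore in part built in. How much came from the offset, the input signal or the correction was not tested. The 772 identifiers lower at both 1.5 and 5 days outnumbered the 739 higher before molt, an order that turned under normexp, under spike-in scaling and with no filter (1050 against 1062).

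Under normexp, identifiers higher and lower than before molt numbered 474 and 853 at 1.5 days, 244 and 1003 at 5 days, and 135 and 451 at 10 days. From 1.5 to 5 days 77 were higher, and from 5 to 10 days 566 were higher and 136 lower. Apart from every other time, 220 were higher and 34 lower before molt, 51 and 5 at 1.5 days, 10 and 104 at 5 days, and 16 and 37 at 10 days. At both 1.5 and 5 days 26 were higher and 213 lower. The SD of repeated spots for 5 days against before molt was 0.097.

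With no filter on dim probes, 2638 were higher at 1.5 days than before molt and 2794 at 5 days, and 1700 were higher and 2611 lower at 10 days. From 1.5 to 5 days 1572 were higher and 1438 lower, and from 5 to 10 days 2740 and 2422. Apart from every other time, 308 were higher and 419 lower at 1.5 days, 463 and 649 at 5 days, and 404 and 660 at 10 days. At both 1.5 and 5 days 445 were higher. The set at least 16-fold lower at 5 days grew from 52 to 80. The SD of repeated spots was 0.45, 0.47 and 0.46 at 1.5, 5 and 10 days against before molt, 0.50 for 5 against 1.5 days and 0.57 for 10 against 5 days.

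With detection required on all 4 arrays, 436 were higher before molt than at each other time, 53 at 1.5 days, 65 at 5 days and 82 at 10 days, and 208 were lower at 10 days. Under spike-in scaling, 199 were higher and 9134 lower at 1.5 days than before molt, 510 and 5335 at 5 days, and 355 and 3482 at 10 days, with 1600 higher and 276 lower from 1.5 to 5 days. Apart from every other time, 2189 were higher and 60 lower before molt, and 13 higher and 753 lower at 1.5 days. At both 1.5 and 5 days 40 were higher and 1483 lower. Spike-in scaling moved the median log2 ratio of all identifiers to -0.91 at 1.5 days, -0.56 at 5 days and -0.46 at 10 days against before molt, and median centring moved it to 0.14, 0.18 and 0.03. Over identifiers with 2 or more probes (chosen after seeing the data), 531 were higher and 570 lower at 1.5 days than before molt, 567 and 516 at 5 days, and 251 and 326 at 10 days.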

Other observations

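Of the tests in this part, that on array position over all probes was set before its result was seen, and those on brighter probes and on the 52 identifiers after it.

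The resemblance of 1.5 to 5 days and of before molt to 10 days was between neighbours on the slide. The arrays of 10 days, before molt, 1.5 days and 5 days lay at positions 1, 2, 3 and 4. It did not extend to the neighbours before molt and 1.5 days (Pearson r 0.946). They were less alike than 10 and 5 days at positions 1 and 4 (0.957). Effects of array position on single probes would leave probes of 1 identifier no more alike than random probes. Their intraclass correlation for 5 days against before molt was 0.41, and the highest of 100 shuffles was 0.03, which argues against such effects as the whole cause. Over all probes it missed the bound of 0.5 set beforehand, while over probes above the 75th percentile it was 0.63, past that bound and above every one of 100 shuffles, and over dimmer probes 0.31. Over probes above the 75th percentile it was 0.48 for 10 days against before molt, under the bound, and 0.65 for 5 days against 1.5 days. An effect shared by all probes of an identifier would not be seen by this test. The SD between probes of 1 identifier was itself smallest for 5 days against 1.5 days (0.34) and largest for 1.5 days against before molt (0.65), as it was over probes above the 75th percentile (0.26 and 0.47), so part of the resemblance may lie in the probes and over all probes cannot be told apart from a difference between times, and a difference between times, birds or RNA preparations was not tested.

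The 52 identifiers with a deep trough at 5 days invite the hypothesis of one RNA source of fixed composition (one tissue, or one structure in the skin) that was present before molt and at 10 days and nearly missing at 5 days. Such a source would give every member the same ratio of 10 days to before molt. Over the 15 members among the 100 brightest identifiers that log2 ratio had an SD of 0.20 (95% bootstrap interval 0.13 to 0.25). This lay below the 0.39 between bright probes of 1 identifier. The bootstrap took identifiers as independent. Near-identical copies of a transcript would be alike by construction, so the bootstrap intervals given here may be too narrow. The 85 other identifiers among the 100 brightest, which had no such trough, also lay below 0.39, at 0.32 (0.27 to 0.36). This bound therefore does not decide for or against one source, and for the 15 members one source stays open. Over the 37 other members the SD was 0.89 (0.63 to 1.09), with log2 ratios from -2.84 to 0.87. It was 0.49 (0.33 to 0.65 over random sets of 37) over identifiers outside the set matched on level and read by 1 probe. Over all matched identifiers it was 0.45 (0.30 to 0.61). The 0.89 lies above both ranges. The median ratio of the 37 was -0.34, so the lowest ratios weigh on the 0.89, and no SD was computed without them. The lower bound of 0.63 for the 0.89 lies above the 0.50 between probes of 1 identifier, though not above 0.65. The SD over the 37 members was thus wider than over matched identifiers, but its lower bound did not clear 0.65. This does not decide for or against a single source of fixed composition for the 37 members. The division into 15 and 37 used mean signal over all arrays, so levels at 5 and 10 days helped to decide it. Part of the difference between the SDs of 0.20 and 0.89 may come from that division. Over all 52, where the division plays no part, the SD was 0.77 (0.53 to 0.95).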
